A study of Homo sapiens with 6 samples.

How the data were processed

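H1 human embryonic stem cells had been differentiated for 72 h under 6 regimes of Activin A and BMP4, with 1 library of the 10x Chromium Single Cell 3' v3 chemistry per regime, sequenced on a HiSeq 4000. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization; per the file headers they are of format version 2 and software version 3.1.0. Per the submitters' processing notes the genome build was GRCh38 and their own work used Scanpy 1.9; the aligner and the gene annotation are not given in the sources used here. Each matrix lists 33540 features, of which 33456 were found by identifier in GENCODE release 29, the source of the positions given. Genes were joined by identifier, since 24 names are shared by more than 1 feature, and the 2 reporter features had 0 UMIs. The labels give no batch. For the series as a whole, the design text and the treatment protocol name different basal media (E5, and TeSR-E6 with additions).

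Barcodes were kept with at least 1000 genes, at least 2000 UMIs and a mitochondrial share of at most 15%, which left 26029 of 32287. Doublets were scored within each library by the share of simulated doublets among a cell's neighbours, and the highest scores were removed up to 0.8% per 1000 barcodes (3.27, 4.48, 7.27, 3.48, 3.26 and 4.07%), 1245 cells in all. Libraries are listed in the order sustained BMP4, A+B 24 h then BMP4, BMP4 48 h then A+B, A+B 48 h then BMP4, BMP4 24 h then A+B, and sustained A+B, where A+B stands for Activin A with BMP4. The kept cells carried 89941088, 155600184, 244581300, 95721362, 122770261 and 125897221 UMIs, with medians of 5073, 5892, 5530, 5500, 5745 and 5731 genes per cell and of 3.31, 4.52, 1.64, 5.29, 3.90 and 5.30% mitochondrial UMIs.

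Cells of all libraries were clustered together without batch correction on log-transformed counts per 10000, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. The 87 marker genes and 326 others (mitochondrial, ribosomal, Y-linked and XIST) were kept out of the genes that made the clusters. A cluster took the name of a list when at least 3 of its markers reached 20 CPM and 3 times the level in other cells, no other list had more markers among the cluster's 10 leading genes, and either at least 1 marker of the list was among those 10 or at least as many of its markers were raised as not. These naming thresholds were set after the clusters had been seen. Marker combinations were counted as cells with at least 1 UMI of every gene after each cell had been thinned to 6000 UMIs, which left out 559 shallower cells and kept 24225. Beside each stands the share in a class that should lack the genes.

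Counts were summed over kept cells per library, and over endoderm-like cells where a library had at least 100. Ratios are log2 values of CPM with a pseudocount of 1, and folds are ratios of CPM. Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95%. With 1 library per regime no test was run and no p-value is given. A list member counted as measured at 5 CPM in either library, and a list's median log2 ratio was placed among 10000 random lists matched on mean expression. There were 11 marker lists (pluripotent, primitive streak, definitive endoderm, nascent or paraxial mesoderm, lateral or extraembryonic mesoderm, amnion, trophoblast, germ cell, axial mesoderm, endothelial or haemogenic, neural or neural crest) and 13 programme lists (BMP response, Nodal-Activin response, WNT, mesenchymal, epithelial, HOX and CDX, retinoic acid, fibrillar matrix, basement membrane, cell cycle, glycolysis and hypoxia, stress and immediate early, p53 response). The genes named are the 10 highest and 10 lowest log2 ratios among named genes at 50 CPM or more in either library, 5 and 5 where a switched library was set against a sustained one, leaving out clone-named, mitochondrial, ribosomal, Y-linked, histone and haemoglobin genes; list and gate members are named besides. Some genes that meet these rules are not printed. Lists, gates, comparisons, thresholds other than those for naming clusters, and the naming rule for genes were fixed before the data were examined.

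The alternatives were no filter on barcodes, a stricter one (3000 genes, 10% mitochondrial), doublets kept, median-of-ratios or TMM scaling, a mean over cells, a pseudocount of 5, list minimums of 20 CPM or none, gates of at least 2 UMIs, no thinning, Leiden resolutions of 0.3 and 1.0, marker genes allowed among the variable genes, 4000 variable genes, 30 neighbours, and endoderm-like cells defined by SOX17 and FOXA2 UMIs. Another pair was added after the data had been seen: leaving out cells under 0.5% mitochondrial UMIs, and naming clusters at 2 times in place of 3. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 for TMM. The ratios were tested on simulated data: intervals held the true ratio for 95.7% of 19944 genes, 100 of 100 genes changed 3-fold were found at least 2-fold apart, and 0 of 2556 unchanged genes were. The simulated counts had Poisson error alone, at the depth of the sustained libraries, and the 2-fold counts used genes at 50 CPM or more. Variation between cells or cultures and the smaller sums of endoderm-like cells were not covered, so this checked the calculation only.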

Results

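Droplet single-cell RNA sequencing was done on H1 cells, an established human embryonic stem cell line, after 72 h of differentiation with Activin A and BMP4. Cells received either Activin A at 100 ng/mL with BMP4 at 10 ng/mL (A+B from here on) or BMP4 at 50 ng/mL alone. There were 6 conditions with 1 library each and no replicates: each cue sustained for 72 h, and each order of the cues with a switch at 24 h or at 48 h. The stated purpose was to learn which cell fates arise with different lengths and orders of these signals, and the series title speaks of more than one route to endoderm. Sets of 6 values are given in a fixed library order: sustained BMP4, A+B for 24 h then BMP4, BMP4 for 48 h then A+B, A+B for 48 h then BMP4, BMP4 for 24 h then A+B, and sustained A+B. In that order the matrices held 97563159, 171717099, 282010287, 105143623, 131701992 and 139894926 UMIs in 4082, 5598, 9087, 4354, 4075 and 5091 barcodes. After filtering and removal of likely doublets, 3200, 4252, 7032, 3116, 3393 and 3791 cells were kept, at medians of 24700, 32402, 30349, 28596, 31962 and 30654 UMIs per cell. Levels are in CPM, a gene's UMIs summed over kept cells and scaled to the total UMIs of those cells. Intervals are 95% and cover counting error only, so none of the differences below was tested against variation between cultures.

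The 24784 kept cells fell into 12 clusters, 7 of which were named from marker lists that had no part in making them. The names gave 6 classes. Pluripotent-like cells carried SOX2, UTF1 and DNMT3B (3 of 8 markers), and endoderm-like cells 7 of 10 definitive endoderm markers with SOX17 and FOXA2 among them. Germ cell-like cells carried NANOS3, TFAP2C and KIT (3 of 6 markers). Nascent or paraxial mesoderm-like cells carried MESP1, TBX6 and DLL3, lateral or extraembryonic mesoderm-like cells HAND1, FOXF1 and PITX1, and amnion-like cells GABRP, IGFBP3 and TFAP2A. The other 5 clusters stayed unnamed and held 17.2, 21.5, 30.8, 39.9, 30.7 and 57.7% of cells. Among them was cluster 1, with the TGF-beta family ligands GDF3 and NODAL among its 10 leading genes and 12.7, 14.1, 17.6, 23.6, 20.8 and 15.3%. Cluster 8 carried the amnion markers TFAP2A, GATA3, ISL1 and WNT6, but at 12.1 CPM of GABRP against 454 CPM in the amnion-like class. With 4 of 10 amnion markers raised and 0 among its 10 leading genes it was left unnamed under thresholds set after the clusters had been seen, and it held 0.656, 2.07, 2.13, 14.8, 4.10 and 12.1% of cells.

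**Figure D1:**
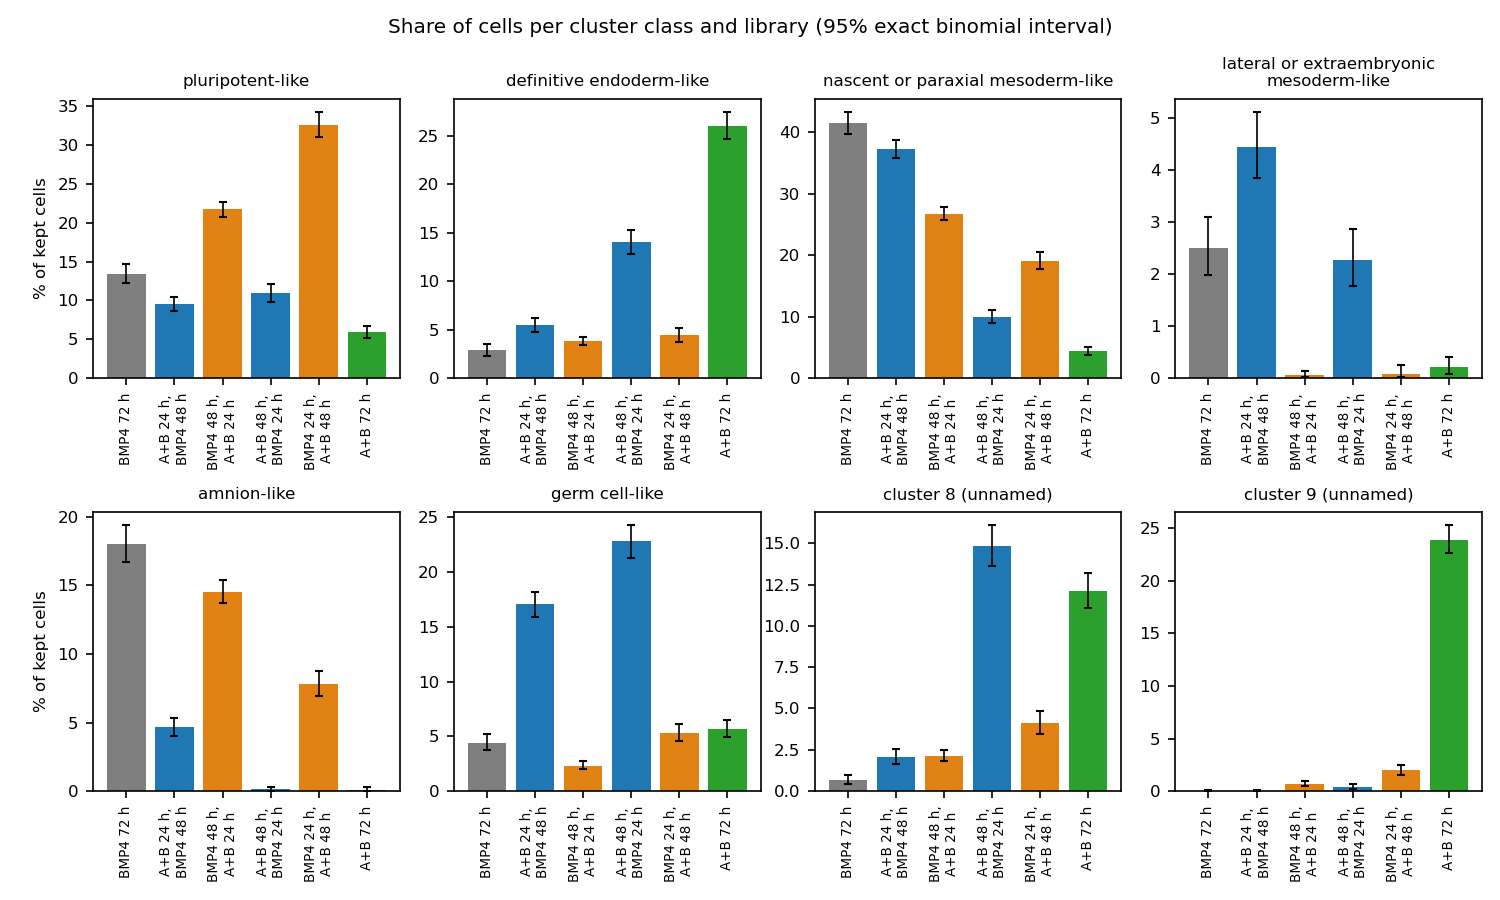
Share of kept cells (%, vertical axis) in each of the 6 named classes and in clusters 8 and 9, for the 6 libraries (grey, sustained BMP4; blue, A+B first; orange, BMP4 first; green, sustained A+B), with 95% exact binomial intervals as error bars. The endoderm-like share was 2.88% with sustained BMP4 and 26.0% with sustained A+B, and the germ cell-like share was 17.1 and 22.8% where A+B came first.

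Sustained A+B and sustained BMP4 were compared to ask what each cue gave when it was not switched. Feedback inhibitors and targets of Nodal and Activin were much higher with A+B. LEFTY1, a secreted Nodal antagonist (ENSG00000243709, GRCh38 chromosome 1, 225886282 to 225911382), was at 288 CPM against 6.42 CPM, 44.9-fold higher (41.4 to 48.9). SOX17, an endoderm transcription factor (ENSG00000164736, chromosome 8, 54457935 to 54460888), was at 210 against 21.6 CPM, 9.71-fold higher (9.27 to 10.2). On the other side stood genes of amnion and mesoderm. IGFBP3, which codes for a secreted binder of insulin-like growth factors (ENSG00000146674, chromosome 7, 45912245 to 45921874), was at 3.50 against 509 CPM, 145-fold lower (132 to 160).

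The endoderm list moved together: all 7 measured members were at least 2-fold higher with A+B, FOXA2 by 11.1-fold, PRDM1 by 6.54-fold, HHEX by 6.32-fold and CXCR4 by 6.25-fold. The list's median log2 ratio was 2.52, at percentile 100.0 of 10000 random lists matched on expression. Of 9 Nodal-Activin response genes 7 were higher (median 2.27), with LEFTY2 16.2-fold, GSC 6.28-fold and CER1 4.84-fold, while MIXL1 and FOXH1 lay within 2-fold. Primitive streak genes split, 4 of 8 higher and 1 lower (median 1.13): FGF17 was 7.12-fold higher and FGF4 2.86-fold lower. All 6 nascent or paraxial mesoderm genes were lower (median -2.80), including TBX6 by 10.0-fold and MESP1 by 4.40-fold, and so were all 5 measured HOX and CDX genes, which pattern the posterior embryo (median -2.99; CDX2 19.7-fold). Of 9 amnion genes 8 were lower (median -2.06), with GABRP, a GABA receptor subunit, 86.4-fold and KRT7 40.6-fold; GATA3 was at 49.1 against 49.9 CPM. Of 8 lateral or extraembryonic mesoderm genes 6 were lower (median -1.68), HAND1 by 7.70-fold and SNAI2 by 15.3-fold, but PITX1 was 6.80-fold higher. Over all libraries PITX1 was at 47.2 CPM in lateral or extraembryonic mesoderm-like cells. It was also at 50.9 CPM in germ cell-like and 27.2 CPM in endoderm-like cells, so its rise does not mark that mesoderm alone.

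Germ cell genes lay on the A+B side, with NANOS3 (3.74-fold) and KIT (2.72-fold) higher and TFAP2C within 2-fold (median 1.33). KIT was at 39.0 CPM in endoderm-like and 37.2 CPM in germ cell-like cells, so its rise does not tell these classes apart. NANOS3 was at 48.4 CPM in germ cell-like cells and also at 15.5 CPM in the unnamed cluster 9, described below. The BMP response genes divided: MSX1, a homeobox target of BMP, was 11.6-fold lower and MSX2 2.23-fold lower, whereas the other 8 of 10, ID1 to ID4 among them, lay within 2-fold (median 0.04). In the WNT list, 2 of 14 members were lower (LEF1 9.51-fold, WNT5A 4.11-fold) and 2 higher (NOTUM 3.22-fold, DKK4 18.0-fold), with a median of 0.01. Among mesenchymal genes SNAI2 and ZEB2 were lower and CDH2 2.58-fold higher (median -0.62). Retinoic acid pathway genes showed CYP26A1, an enzyme that degrades retinoic acid, 10.4-fold higher and CRABP2 4.49-fold lower (median -0.65). Fibrillar matrix genes LUM and COL3A1 were 26.9-fold and 15.4-fold lower (median -0.33), and basement membrane genes COL4A1 and COL4A2 3.36-fold and 2.44-fold higher (median -0.12). Of 8 pluripotency genes TDGF1, a Nodal co-receptor, was 2.26-fold higher and UTF1 2.68-fold lower, and POU5F1 differed by 1.29-fold (median 0.09). None of the 8 epithelial genes (median -0.11), 13 cell cycle genes (-0.02) or 9 glycolysis and hypoxia genes (0.13) differed by 2-fold. EGR1 in the stress and immediate early list was 3.47-fold lower (median -0.10) and GDF15 in the p53 response list 6.49-fold higher (median 0.42). Lists of cell types with few measured genes gave 1 of 2 trophoblast genes lower (GATA2 5.78-fold), 1 axial mesoderm gene within 2-fold (NOG), 1 neural gene lower (SIX3 13.9-fold) and, of 4 endothelial or haemogenic genes, CD34 higher and SOX7 11.9-fold lower. CD34 was at 6.78 against 0.0889 CPM.

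The genes with the largest ratios also included, on the A+B side, PLSCR2 (38.0-fold), MATN3 (10.6-fold), FAM184A (7.64-fold) and the protocadherin PCDH10 (6.26-fold), and on the BMP4 side the hypoxia-inducible factor EPAS1 (153-fold), TCIM (33.3-fold), the growth factor PTN (21.3-fold) and LCP1 (13.8-fold). In all, 86 of 2957 genes at 50 CPM or more were at least 2-fold higher with A+B and 49 at least 2-fold lower. The cells differed in the same sense. Endoderm-like cells made up 26.0% (24.6 to 27.4) with A+B and 2.88% (2.32 to 3.51) with BMP4, while nascent or paraxial mesoderm-like cells were 4.41 against 41.6% and amnion-like cells 0.106 against 18.0%, or 12.2 against 18.7% with cluster 8 added. Lateral or extraembryonic mesoderm-like cells were 0.211 against 2.5%, pluripotent-like cells 5.91 against 13.4% and germ cell-like cells 5.70 against 4.41%. Cluster 1, which is not counted among pluripotent-like cells, was 15.3 against 12.7%. Cluster 9 expressed SOX17 at 231 CPM, PRDM1 at 98.1 CPM and the germ cell gene TFAP2C at 78.8 CPM, with FOXA2 at 26.7 CPM. It held 23.9% of sustained A+B cells and 0 of 3200 sustained BMP4 cells (upper 95% bound 0.115%). These shares moved with the clustering: with marker genes allowed or doublets kept the endoderm-like share with sustained A+B was 49.8 and 49.3%, and at resolution 0.3 or with 4000 variable genes the germ cell-like share there was 21.3 and 19.8%. At resolution 0.3 the nascent or paraxial mesoderm-like share with sustained A+B was 10.6%, and at resolution 1.0 the lateral or extraembryonic mesoderm-like share with sustained BMP4 was 8.47%. The sustained BMP4 library had more cells with almost no mitochondrial UMIs (11.8% under 0.5%, against 1.21%), and without them its amnion-like share was 13.3%.

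**Figure D2:**
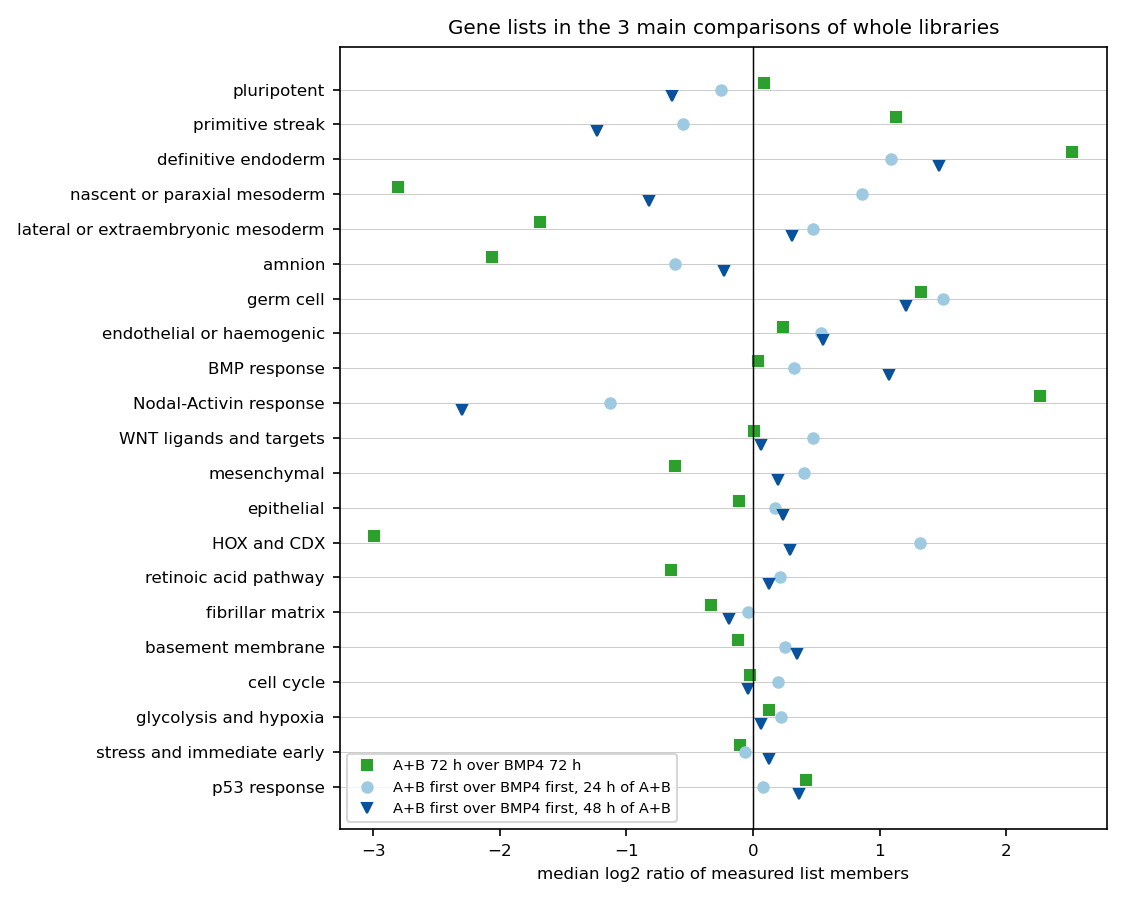
Median log2 ratio (horizontal axis) of the measured members of 21 fixed gene lists in whole libraries, for sustained A+B over sustained BMP4 and for A+B first over BMP4 first with 24 h or 48 h of A+B in all. Nodal-Activin response genes had medians of 2.27, -1.13 and -2.30 and definitive endoderm genes 2.52, 1.09 and 1.47.

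The effect of order was asked first with 24 h of A+B and 48 h of BMP4 in both libraries, A+B coming first or last. In each comparison of orders the A+B-first library ended in BMP4 alone and the BMP4-first library in A+B. Order thus cannot be told apart from the cue present at the end. Where A+B came first, genes of germ cells and of endoderm, some of them high in both classes, were higher and Nodal-Activin targets lower. TFAP2C, a germ cell and trophoblast transcription factor (ENSG00000087510, chromosome 20, 56629302 to 56639283), was at 58.5 against 16.3 CPM, 3.59-fold higher (3.46 to 3.73), and the growth factor gene IGF1 was at 68.5 against 10.4 CPM, 6.61-fold higher (6.33 to 6.90). CER1, a secreted antagonist of Nodal and BMP that is also an endoderm marker (ENSG00000147869, chromosome 9, 14719724 to 14722717), was at 173 against 779 CPM, 4.51-fold lower (4.45 to 4.57).

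Of 7 endoderm genes 4 were higher, CXCR4 by 3.84-fold, PRDM1 by 3.23-fold, FOXA2 by 2.37-fold and SOX17 by 2.33-fold, and CER1 was lower (median 1.09). SOX17, PRDM1 and CXCR4 were also high in germ cell-like cells (257, 115 and 84.8 CPM over all libraries). In endoderm-like cells they were at 491, 113 and 131 CPM, so their rise does not tell these classes apart. FOXA2 was at 10.8 CPM in germ cell-like and 144 CPM in endoderm-like cells. Nodal-Activin response genes were lower in 5 of 9 (median -1.13), among them LEFTY1 by 6.89-fold and GSC by 3.65-fold, and none was at least 2-fold higher. Of 6 HOX and CDX genes 5 were higher (median 1.32; CDX2 5.53-fold, HOXB5 3.84-fold). NANOS3 and TFAP2C of 3 germ cell genes were higher (median 1.5), and DLL1 and RSPO3 of 6 nascent or paraxial mesoderm genes (median 0.86). In the streak list TBXT was 2.26-fold higher and FGF8 4.25-fold lower (median -0.55). GABRP (3.92-fold), IGFBP3 (2.41-fold) and VTCN1 were lower among 9 amnion genes (median -0.62). BMP response genes differed little except MSX1, 2.59-fold higher (median 0.32).

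Other genes higher with A+B first were PLBD1 (2.85-fold), the long noncoding RNA PCAT14 (2.79-fold), RAB15 (2.65-fold), ASRGL1 (2.62-fold), SAT1 (2.5-fold), the proton channel gene HVCN1 (2.45-fold) and the apelin receptor gene APLNR (2.33-fold). Lower were the matrix proteoglycan gene LUM (5.91-fold), ANKRD1 (5.84-fold), PTN (4.80-fold), IGFBP7 (4.42-fold), PMP22 (3.95-fold), CSRP1 (3.44-fold), TCIM (3.44-fold) and the tropomyosin gene TPM1 (3.26-fold). In all, 14 of 2889 genes were at least 2-fold higher and 22 at least 2-fold lower. Cells under 0.5% mitochondrial UMIs were 2.99% with A+B first and 9.85% with BMP4 first, and without them the counts were 15 and 16. Germ cell-like cells were 7.31 times as frequent with A+B first (17.1 against 2.33%) and lateral or extraembryonic mesoderm-like cells were 4.44 against 0.0569%. Nascent or paraxial mesoderm-like cells were 37.3 against 26.8% and endoderm-like cells 5.48 against 3.83%. Pluripotent-like cells were 9.52 against 21.7% and amnion-like cells 4.66 against 14.5%. Cluster 1, not counted among pluripotent-like cells, was 14.1 against 17.6%. No lateral class was found at resolution 0.3, with marker genes allowed or over every barcode.

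With 48 h of A+B and 24 h of BMP4 in both libraries, the endoderm, Nodal-Activin, streak and BMP response lists had medians further from 0 than with 24 h of A+B. The HOX and CDX, germ cell and WNT lists had medians nearer to 0 (0.29, 1.21 and 0.06 against 1.32, 1.5 and 0.47), and the differences between durations were not tested. CST1, which codes for a secreted cystatin (ENSG00000170373, chromosome 20, 23747553 to 23751268), was at 109 CPM where A+B came first and 0.945 CPM where BMP4 came first, 115-fold higher (95.8 to 139). CER1 was at 56.8 against 494 CPM, 8.70-fold lower (8.46 to 8.94), and IGFBP3 at 7.35 against 137 CPM, 18.7-fold lower (17.3 to 20.2). GATA3, a transcription factor of amnion and trophoblast, was at 94.0 against 29.9 CPM, 3.14-fold higher (3.02 to 3.26).

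Endoderm genes were higher in 6 of 8 (median 1.47), FOXA2 by 3.51-fold and SOX17 by 2.75-fold, with HHEX (4.27-fold) and CER1 lower. SOX17 was high in germ cell-like cells too, as said above. Nodal-Activin response genes were lower in 7 of 9 (median -2.30), LEFTY2 by 16.9-fold, GSC by 8.17-fold and NODAL itself by 3.03-fold. Of 8 streak genes 7 were lower (median -1.23), among them MIXL1 by 4.98-fold and TBXT by 2.22-fold. BMP response genes went the other way, 6 of 10 higher (median 1.07), with MSX1 at 2.77-fold, ID4 at 2.70-fold and ID2 at 2.11-fold. The amnion list divided: TFAP2A (2.58-fold) and GATA3 were higher, GABRP (21.3-fold) and IGFBP3 lower (median -0.23). Like GATA3, TFAP2A was high in another class too, at 98.6 CPM in germ cell-like cells against 164 CPM in amnion-like cells. NANOS3 (5.47-fold) and TFAP2C (2.36-fold) were again the 2 of 3 germ cell genes that were higher (median 1.21). In the nascent or paraxial mesoderm list 1 of 5 genes, TBX6, was lower past the threshold, at 4.23 against 10.1 CPM (median -0.82).

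CRHBP, which binds corticotropin-releasing hormone, was 32.2-fold higher, followed by PCAT14 (5.44-fold), FAM184A (4.29-fold), the claudin gene CLDN10 (4.12-fold), S100A16 (4.01-fold), HPGD (3.73-fold), PEG10 (3.01-fold) and CST3 (2.91-fold). IGFBP5 (23.4-fold), IGFBP7 (7.80-fold), PMP22 (4.86-fold), PTN (3.66-fold) and CYP26A1 (3.36-fold) were lower. In all, 31 of 2868 genes were at least 2-fold higher and 23 at least 2-fold lower. Endoderm-like cells were 14.0% (12.8 to 15.3) where A+B came first and 4.45% (3.78 to 5.20) where BMP4 came first, and germ cell-like cells 22.8 against 5.33%. Pluripotent-like cells were 10.9 against 32.6%, nascent or paraxial mesoderm-like cells 10.0 against 19.1% and lateral or extraembryonic mesoderm-like cells 2.28 against 0.0884%. Cluster 1, not counted among pluripotent-like cells, was 23.6 against 20.8%. Amnion-like cells were 0.128 against 7.78%, but at resolution 1.0 and with 4000 variable genes the share with A+B first was 14.2 and 13.1%, above the 10.3 and 10.2% with BMP4 first. With cluster 8 added to the amnion-like class the shares were 15 and 11.9%.

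A period of BMP4 before A+B was set against sustained A+B. With 72 h in all, 24 h and 48 h of BMP4 left 48 h and 24 h of A+B. The length of the BMP4 period thus cannot be told apart from the shorter time in A+B. Endoderm genes were lower after either period and amnion genes higher. CXCR4, a chemokine receptor gene used as an endoderm marker, was 6.87-fold lower after 24 h of BMP4 and 11.4-fold lower after 48 h. SOX17 was 4.64-fold and 7.12-fold lower, and FOXA2 6.92-fold and 9.05-fold lower. Of 7 endoderm genes 6 were lower in each comparison (medians -2.19 and -2.79), with CER1 the exception. IGFBP3 was 39.2-fold and 106-fold higher, and GABRP 39.7-fold and 73.7-fold. Amnion genes were higher in 6 of 8 and 7 of 9 (medians 1.94 and 1.93), nascent or paraxial mesoderm genes in 5 of 5 and 6 of 6 (1.47 and 1.92), and pluripotency genes SOX2 and UTF1 in both. Nodal-Activin response genes were lower in 3 of 9 after either period (medians -0.75 and -0.78), LEFTY1 by 5.90-fold and 9.30-fold.

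After 24 h of BMP4, IGFBP5 (11.8-fold), IGFBP7 (6.26-fold) and PTN (4.66-fold) were also higher, and PLSCR2 (9.70-fold), MATN3 (7.39-fold) and FAM184A (6.11-fold) lower. After 48 h, EPAS1 (110-fold), TCIM (37.2-fold) and LUM (21.5-fold) were higher, and PRDM1 (7.75-fold) and PLSCR2 (7.14-fold) lower. At least 2-fold higher and lower were 29 and 57 of 2931 genes after 24 h, and 40 and 73 of 2972 after 48 h. The endoderm-like share was 4.45 and 3.83% against 26.0%, 5.84 and 6.79 times lower. Pluripotent-like cells were 32.6 and 21.7% against 5.91%, and nascent or paraxial mesoderm-like cells 19.1 and 26.8% against 4.41%. Cluster 1, not counted among pluripotent-like cells, was 20.8 and 17.6% against 15.3%. Amnion-like cells were 7.78 and 14.5% against 0.106%, but with cluster 8 added 11.9 and 16.6% against 12.2%, which left the difference after 24 h within counting error. Cluster 10, with the streak genes MIXL1, EOMES and GSC and the highest CER1 level of any cluster (3830 CPM), was present in the 3 libraries that ended in A+B (6.46, 3.48 and 6.20%) and at 0.0625, 0.0706 and 0.0321% in those that ended in BMP4.

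A period of A+B before BMP4 was set against sustained BMP4 in the same way, and again a longer first period meant a shorter second. SOX17 was 3.18-fold higher after 24 h of A+B and 5.74-fold higher after 48 h, and NANOS3 3.48-fold and 8.02-fold higher (ENSG00000187556, chromosome 19, 13862063 to 13880757; 6.62 and 15.2 against 1.90 CPM). GABRP was 4.59-fold and 46.4-fold lower. Endoderm genes were higher in 3 of 6 and 5 of 7 (medians 1.16 and 1.83), and CER1 was 3.09-fold lower after 48 h. SOX17, PRDM1 and CXCR4 were high in germ cell-like cells too, so their levels do not tell those cells from endoderm-like cells. Amnion genes were lower in 4 of 9 in each comparison (medians -0.82 and -0.56). Mesoderm differed between the periods. After 24 h all 6 nascent or paraxial mesoderm genes lay within 2-fold (median 0.03), and after 48 h all 6 were lower (median -1.94), TBX6 by 5.18-fold and MESP1 by 2.85-fold. HOX and CDX genes followed, with 0 of 6 and 3 of 5 lower (medians -0.05 and -1.23), while BMP response genes were higher in 0 of 10 and 3 of 10 (0.09 and 0.79).

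After 24 h of A+B, IGF1 (3.12-fold), PLBD1 (2.98-fold), PCAT14 (2.44-fold) and TFAP2C (2.31-fold) were also higher, and LUM (7.39-fold), PTN (6.22-fold), LCP1 (4.81-fold) and ANXA1 (4.15-fold) lower. After 48 h, CST1 (49.9-fold), CRHBP (14.6-fold), CLDN10 (10.3-fold) and PCAT14 (7.49-fold) were higher, and IGFBP3 (69.2-fold), LUM (80.4-fold), EPAS1 (35.1-fold) and PTN (16.7-fold) lower. At least 2-fold higher and lower were 10 and 17 of 2850 genes after 24 h, and 41 and 39 of 2892 after 48 h. Endoderm-like cells were 5.48 and 14.0% against 2.88%, germ cell-like cells 17.1 and 22.8% against 4.41%, and amnion-like cells 4.66 and 0.128% against 18.0%. With cluster 8 added the last were 6.73 and 15% against 18.7%, and the share after 48 h was 14.2% at resolution 1.0 and 13.1% with 4000 variable genes. Nascent or paraxial mesoderm-like cells were 37.3 and 10.0% against 41.6%; where a marker counted as raised at 2 times the level of other cells the class narrowed to 1 cluster, with 13.2 and 3.02% against 10.3%. Pluripotent-like cells were 9.52 and 10.9% against 13.4%, but at resolution 1.0 the share after 48 h, 8.86%, was above the 7.81% of sustained BMP4. Cluster 1, which had pluripotency genes but is not counted among these cells, was 14.1 and 23.6% against 12.7%. A lower share of cells with pluripotency genes after 48 h is thus not shown.

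Pairs of marker genes in the same cell gave shares that did not depend on clusters. Each cell was thinned to 6000 UMIs, and 149, 58, 249, 27, 36 and 40 shallower cells were left out. Cells with both SOX17 and FOXA2 (ENSG00000125798, chromosome 20, 22581005 to 22585455) made up 1.57, 3.96, 1.86, 8.03, 2.35 and 15.2% of cells, and 2.59, 8.16, 3.78, 16.8, 5.04 and 30.5% without thinning. Of those found without thinning, 84.3, 58.5, 77.4, 72.6, 67.8 and 72.7% were in the endoderm-like class. Among pluripotent-like cells, which should lack both, 0 of 410, 400, 1462, 336, 1098 and 216 cells had them, at median depths of 28576, 40320, 34780, 30955, 33653 and 34410 UMIs against the library medians given above. The germ cell combination of SOX17, TFAP2C and NANOS3 was seen in 0.492, 1.76, 0.147, 3.40, 0.447 and 0.853% of cells, and in 1.56, 8.61, 1.11, 14.2, 3.24 and 8.86% without thinning. No nascent or paraxial mesoderm-like cell had it, at median depths of 23468, 31021, 25747, 26742, 27024 and 30826 UMIs. With at least 2 UMIs of each gene it was too rare to order sustained A+B and sustained BMP4 (0.0267 and 0.0328%).

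MESP1 with TBX6, a pair of nascent mesoderm, was found in 10.3, 9.73, 5.82, 1.65, 4.97 and 0.587% of cells (26.1, 29.5, 17.5, 6.32, 16.2 and 3.19% without thinning), and HAND1 with FOXF1 in 6.46, 5.39, 2.52, 1.88, 1.40 and 0.427% (17.2, 17.7, 9.54, 5.36, 6.10 and 2.40%). Neither pair was seen in pluripotent-like cells. GATA3 with TFAP2A was highest where A+B for 48 h was followed by BMP4: 5.60, 4.91, 3.54, 14.5, 3.49 and 3.28% (17.9, 19.8, 16.4, 40.9, 17.7 and 19.7%), with at most 0.298% of pluripotent-like cells in any library. Over all libraries these genes were at 58.9 and 98.6 CPM in germ cell-like cells, against 125 and 164 CPM in amnion-like cells. The pair thus does not mark amnion-like cells alone. The order of the other 5 libraries for this pair changed without thinning. TBXT with MIXL1, a streak pair, was found in 12.3, 15.7, 10.5, 3.40, 14.3 and 7.46% of cells, but without thinning in 29, 37.5, 25.4, 15.1, 31.3 and 29.2%, where sustained A+B and sustained BMP4 no longer differed. POU5F1 with SOX2 was found in 20.9, 20.6, 32.5, 22.2, 40.0 and 14.3% (26.7, 28.5, 45.0, 30.6, 52.3 and 20.5%). Amnion-like cells, the reference for these pairs, had TBXT with MIXL1 in at most 1.59% and POU5F1 with SOX2 in at most 2.79%, at median depths of 19331, 48710, 24682, 43206, 49548 and 84308 UMIs, and were only 4 cells in A+B for 48 h then BMP4 and in sustained A+B. TBXT with FOXA2, a pair of anterior streak and axial cells, was rare at 0.0656, 0.477, 0.192, 0.388, 0.357 and 0.453% (0.594, 3.65, 1.37, 2.82, 2.83 and 4.38%) and was seen in no amnion-like cell.

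Single genes of these pairs were seen, after thinning, in the following shares of cells. SOX17 was seen in 5.80, 18.7, 6.93, 32.0, 10.7 and 47.9%, and FOXA2 in 1.84, 4.58, 2.40, 9.84, 3.19 and 17.4%. MIXL1 was seen in 37.6, 38.1, 43.8, 16.3, 41.2 and 58.8%, and TBXT in 17.4, 22.5, 12.6, 8.09, 17.5 and 11.5%. For MESP1 the shares were 39.5, 39.9, 30.6, 13.6, 24.9 and 10.3%, for TBX6 12.3, 11.5, 7.06, 2.33, 6.32 and 1.23%, for HAND1 55.7, 43.6, 42.3, 31.2, 26.9 and 14.6% and for FOXF1 6.82, 5.94, 2.90, 2.14, 1.73 and 0.507%. GATA3 was seen in 16.0, 15.5, 11.7, 35.7, 10.9 and 23.0%, TFAP2A in 17.1, 15.5, 12.1, 28.4, 11.7 and 9.78%, TFAP2C in 8.33, 18.1, 6.74, 23.8, 11.6 and 14.0% and NANOS3 in 1.18, 3.46, 0.840, 7.48, 1.28 and 3.65%. POU5F1 was seen in 86.6, 91.1, 88.2, 93.6, 96.2 and 91.8%, and SOX2 in 21.3, 20.8, 32.8, 22.5, 40.1 and 14.3%.

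**Figure D3:**
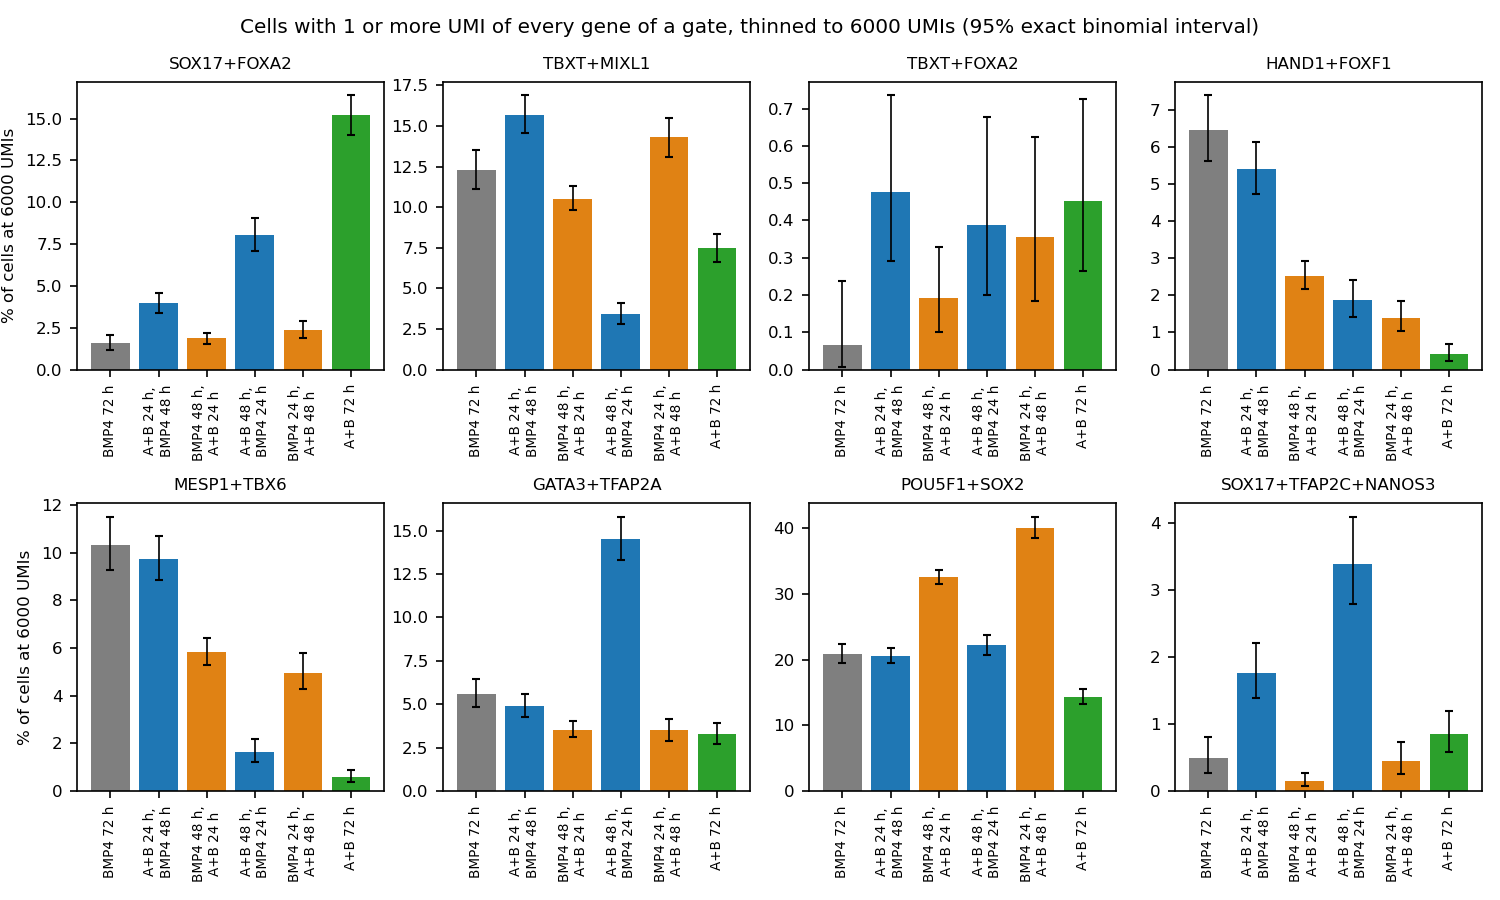
Share of cells (%, vertical axis) with at least 1 UMI of every gene of 8 marker combinations after thinning to 6000 UMIs per cell, for the 6 libraries (colours by order of cues), with 95% exact binomial intervals as error bars. SOX17 with FOXA2 ranged from 1.57% with sustained BMP4 to 15.2% with sustained A+B, and GATA3 with TFAP2A reached 14.5% in A+B for 48 h then BMP4.

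Whether endoderm reached by different orders of cues was alike in expression was asked within the endoderm-like class. Sustained BMP4 gave 92 such cells and was left out, and the other libraries gave 233, 269, 436, 151 and 985 cells. SOX17 (468, 454, 428, 553 and 524 CPM) and FOXA2 (153, 126, 133, 122 and 154 CPM) were at like levels in these cells, which is partly fixed by their part in naming the class. The Nodal-Activin response differed. LEFTY1 was at 6.76, 111, 14.9, 255 and 1096 CPM, so cells that ended in BMP4 stood lowest: 162-fold (124 to 216) and 73.3-fold (63.3 to 85.3) below sustained A+B after A+B for 24 h and 48 h. LEFTY1, FOXQ1, CST1, CST4 and APOA1 were among the genes that set this cluster apart, so their levels within it are partly a matter of its definition.

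Endoderm-like cells after A+B for 24 h then BMP4 had 8 of 9 Nodal-Activin response genes lower than in sustained A+B (median -2.50), CER1 by 14.7-fold (119 against 1747 CPM), GSC by 31.7-fold and LEFTY2 by 145-fold (56.5 to 532, on 4 UMIs). BMP response genes were higher in 5 of 10 (median 1.10), with MSX1 (ENSG00000163132, chromosome 4, 4859666 to 4863936) at 110 against 5.29 CPM, 20.8-fold higher (17.4 to 25.0), and ID2 3.78-fold higher. All 4 HOX and CDX genes measured were higher (median 2.84), as were 5 of 5 nascent or paraxial mesoderm genes (1.65; RSPO3 19.4-fold), 4 of 5 amnion genes (1.84), 2 of 2 trophoblast genes (2.35) and 3 of 7 lateral or extraembryonic mesoderm genes (0.66). The genes with the largest ratios also included HAND1 (11.9-fold), the cardiac actin gene ACTC1 (10.8-fold), CRHBP (7.43-fold), the integrin gene ITGA6 (7.13-fold), GAD1 (7.01-fold), TMEM88 (6.70-fold), RGS5 (ENSG00000143248, 6.24-fold), HPGD (6.14-fold) and HLA-B (5.64-fold) as higher. FREM1 (42.4-fold), FOXQ1 (20.0-fold), PLSCR2 (16.9-fold), TDRD7 (8.71-fold) and the WNT receptor gene FZD5 (8.40-fold) were lower. In all, 56 of 3120 genes were at least 2-fold higher and 89 lower. With marker genes allowed in the clustering, where the class held 49.8% of sustained A+B cells, HPGD turned to a log2 ratio of -0.80 from 2.52, HAND1 came to 1.64 from 3.33 and CER1 to -2.81 from -3.87. With the cells taken by SOX17 and FOXA2 UMIs alone, LEFTY2 came to -1.79 from -5.62 and ACTC1 to 1.78 from 3.28. Of 347 such cells after A+B for 24 h then BMP4, 58.5% were in the endoderm-like class, and of 1158 with sustained A+B 72.7%. This alternative thus took in cells of other classes. LEFTY2 was at 78.3 CPM in germ cell-like cells of the former library, against 0.501 CPM in endoderm-like cells.

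After A+B for 48 h then BMP4, Nodal-Activin response genes were lower in 7 of 9 (median -4.14), GSC by 67.2-fold, CER1 by 26.2-fold and NODAL by 21.1-fold; LEFTY2 had 2 UMIs, for a ratio between 122 and 3633. BMP response genes were higher in 7 of 10 (median 1.65), with ID2 at 359 against 56.6 CPM, 6.35-fold higher (5.99 to 6.74), and MSX1 at 7.79-fold. Streak genes were lower in 5 of 6 (median -2.75), and the endoderm gene HHEX by 11.4-fold. Higher too were APELA, which codes for a ligand of the apelin receptor (42.5-fold), HPGD (23.2-fold), CST4 (10.6-fold), CRHBP (8.14-fold), TMEM88 (8.04-fold), CST1 (7.28-fold), PITX1 (7.09-fold), HLA-B (6.56-fold) and RGS5 (6.28-fold), and lower FREM1 (48.8-fold), FOXQ1 (33.2-fold), FZD5 (10.3-fold) and PLSCR2 (8.97-fold). In all, 67 of 3062 genes were at least 2-fold higher and 100 lower. With marker genes allowed in the clustering, APELA came to a log2 ratio of 1.73 from 4.55 and HPGD to 0.56 from 4.43, and 61 genes were lower.

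Endoderm-like cells that had BMP4 first were closer to sustained A+B, with which they shared A+B as the last cue. After BMP4 for 24 h then A+B, 2 of 3026 genes were at least 2-fold higher, the WNT modulator gene SFRP2 (2.35-fold) and ID2 (2.05-fold), and 40 lower. FOXQ1 (31.0-fold), CST1 (13.4-fold), S100A14 (6.79-fold), STC1 (4.74-fold), the apolipoprotein gene APOA2 (4.72-fold), RAB17 (4.44-fold), LEFTY1 (4.30-fold), TNNC1 (4.17-fold), the glucose transporter gene SLC2A3 (3.81-fold) and S100A10 (3.45-fold) stood lowest, and RAB31 (1.92-fold), ROBO1 (1.80-fold), NTS (1.79-fold), CRMP1 (1.79-fold), IGFBP2 (1.76-fold), RHOB (1.75-fold), CRABP1 (1.73-fold) and BEX2 (1.65-fold) were higher by less than 2-fold. After BMP4 for 48 h then A+B, 10 of 3083 genes were at least 2-fold higher, MSX1 (9.87-fold), ACTC1 (8.50-fold), the natriuretic peptide gene NPPB (6.0-fold), SFRP2 (2.84-fold), CACHD1 (2.34-fold), IFI16 (2.30-fold), ANKRD1 (2.17-fold), ROBO1 (2.09-fold), PKN2 (2.08-fold) and CRABP1 (2.06-fold), and 48 lower. FOXQ1 (12.6-fold), LEFTY2 (10.4-fold), LEFTY1 (9.88-fold), CST1 (7.0-fold), PLSCR2 (4.59-fold), S100A14 (4.17-fold), CXCR4 (3.74-fold), APOA2 (3.60-fold), FZD5 (3.44-fold) and RAB17 (3.43-fold) were the lowest. Nodal-Activin response genes were lower in 2 of 9 and 4 of 9 (medians -0.58 and -0.92), stress and immediate early genes in 1 of 7 and 3 of 7 (-0.73 and -0.59), and CER1 was at 1679 and 1699 CPM after 24 h and 48 h of BMP4 against 1747 CPM. The Nodal-Activin median after 24 h was 0.01 with marker genes allowed in the clustering, and SFRP2 then came to log2 ratios of 0.41 and 0.32 from 1.20 and 1.47.

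Set against each other at matched hours, endoderm-like cells differed with order, and so with the last cue. With 24 h of A+B, cells that had A+B first showed CST1 at 344 against 12.4 CPM, 27.8-fold higher (22.4 to 34.9), and the fibronectin gene FN1 at 1630 against 401 CPM, 4.06-fold higher (3.90 to 4.23). CER1 was at 119 against 1699 CPM, 14.3-fold lower (13.4 to 15.3), and Nodal-Activin response genes were lower in 6 of 9 (median -1.92). CST4 (38.7-fold), CRHBP (21.3-fold), TMEM88 (8.93-fold), APOA1 (6.63-fold), RGS5 (5.32-fold), FBLN2 (4.38-fold), HLA-B (4.30-fold) and TNNC1 (4.05-fold) were higher. FREM1 (20.3-fold), LEFTY1 (16.4-fold), GSC (14.3-fold), CYP26A1 (3.84-fold), MIXL1 (3.82-fold), PLSCR2 (3.68-fold), TAGLN (3.26-fold), C1orf61 (3.06-fold) and FGF17 (2.95-fold) were lower. In all, 45 of 3100 genes were at least 2-fold higher and 28 lower. With cells taken by SOX17 and FOXA2 UMIs the counts were 38 and 41, and CRHBP came to a log2 ratio of 1.79 from 4.27. Of the cells so taken, 58.5% with A+B first and 77.4% with BMP4 first were in the endoderm-like class.

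With 48 h of A+B, 120 of 3091 genes were at least 2-fold higher where A+B came first and 51 lower. CST1 was at 631 against 6.49 CPM, 97.2-fold higher (65.8 to 150), and HPGD at 283 against 9.08 CPM, 31.2-fold higher (22.4 to 44.9). Epithelial genes KRT8, KRT18, KRT19 and EPCAM were higher, 4 of 8 on their list (median 0.91), as were 4 of 7 basement membrane genes (1.05) and 5 of 10 BMP response genes (1.14). Stress and immediate early genes FOS, JUN, EGR1 and DDIT3 were higher too and ATF3 lower, of 7 measured (1.12). Nodal-Activin response genes were lower in 7 of 9 (median -3.15) and streak genes in 6 of 7 (-2.08). CRHBP (27.9-fold), TMEM88 (26.2-fold), S100A14 (23.4-fold), APELA (21.5-fold), PITX1 (15-fold), TNNC1 (14.9-fold) and RGS5 (11.1-fold) were higher, with CST4 at 3 UMIs on the other side, for a ratio between 62.2 and 884. Lower were FREM1 (34.3-fold), GSC (34.1-fold), CER1 (25.2-fold), LEFTY1 (17.1-fold), CALB1 (8.35-fold), C1orf61 (7.52-fold), MIXL1 (6.87-fold), APOBEC3G (5.57-fold), PLXNA2 (5.49-fold) and FGF17 (4.27-fold). With marker genes allowed in the clustering HPGD came to a log2 ratio of 1.32 from 4.82 and APELA to 1.80 from 3.94.

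**Figure D4:**
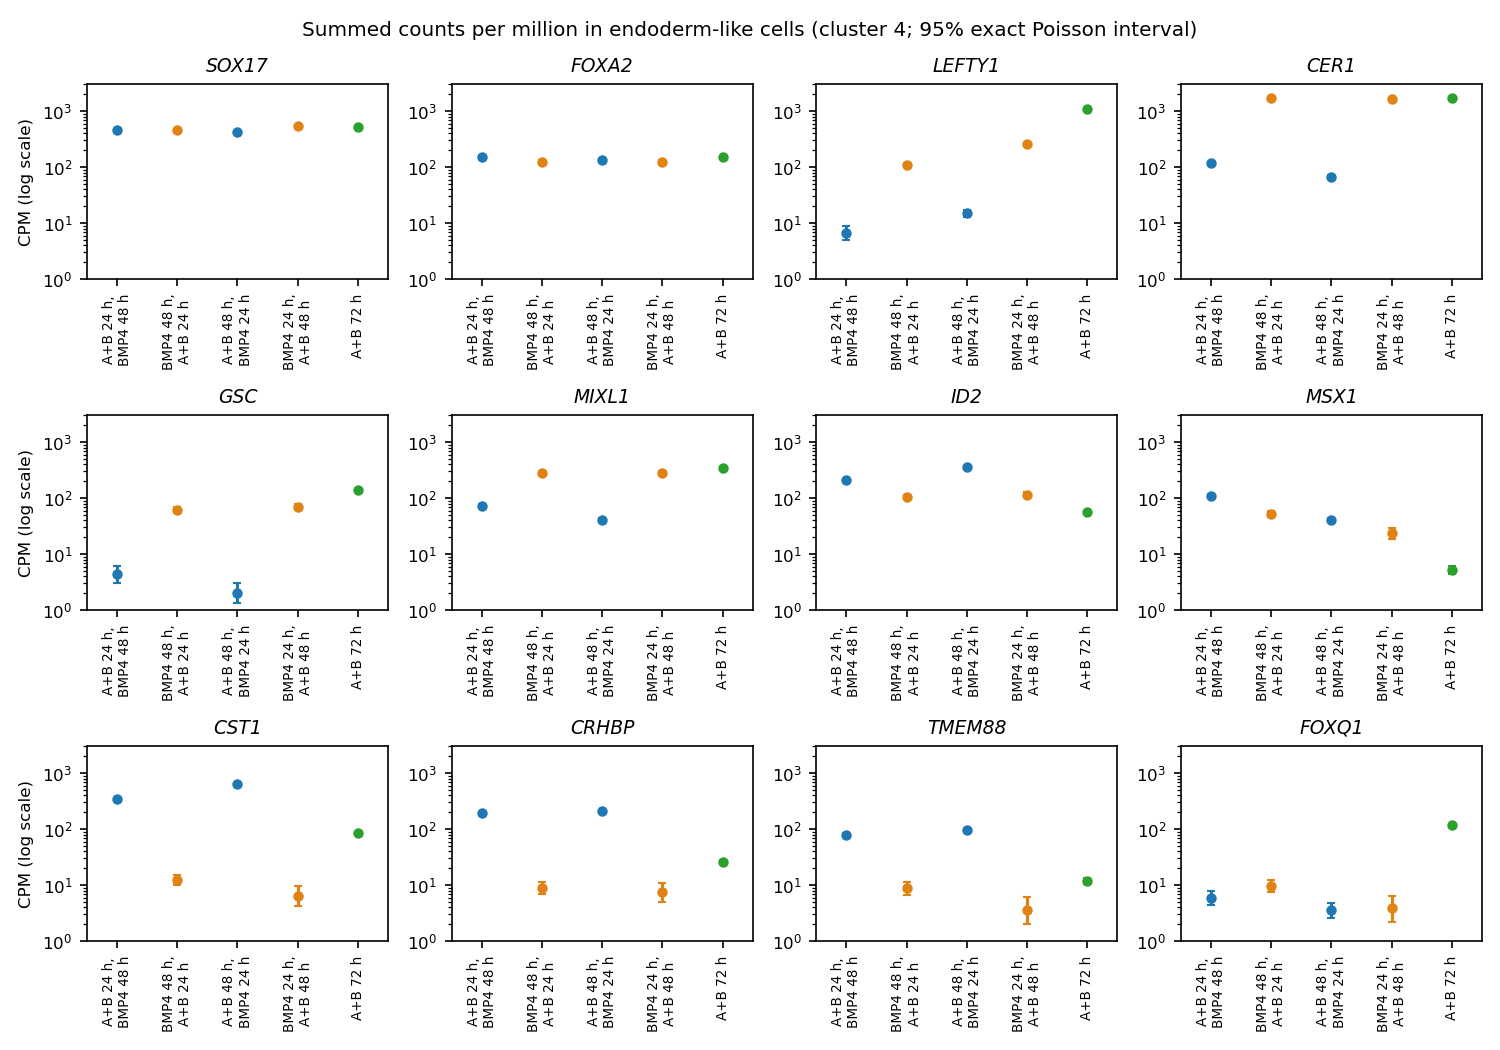
Level (CPM, logarithmic vertical axis) of 12 genes in endoderm-like cells of the 5 libraries with at least 100 such cells, with 95% Poisson intervals as error bars. SOX17 lay between 428 and 553 CPM in all 5, whereas LEFTY1 ran from 6.76 CPM in A+B for 24 h then BMP4 to 1096 CPM in sustained A+B.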

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

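Of the tests given here, those of depth for germ cell-like cells and of doublets for cluster 9 were chosen only after the result was seen. The list median of nascent or paraxial mesoderm genes, the share of such cells and the streak pair went opposite ways with order at 24 h and at 48 h of A+B. This difference between the durations was not tested. Lateral or extraembryonic mesoderm-like cells did not: they were more frequent with A+B first at both (4.44 against 0.0569% and 2.28 against 0.0884%), on 4 and 3 cells with BMP4 first, with list medians of 0.47 and 0.31. Cells with HAND1 and FOXF1 were 5.39 against 2.52% and 1.88 against 1.40%, the latter with overlapping intervals and turned without thinning (5.36 against 6.10%). Nascent or paraxial mesoderm-like cells were 10.5 percentage points more frequent with A+B first at 24 h of A+B, and the difference was -9.1 points at 48 h. Cells with TBXT and MIXL1 differed by 5.21 and -10.9 points, and cells with MESP1 and TBX6 by 3.90 and -3.32 points. The median log2 ratio of the nascent or paraxial mesoderm list was 0.86 and -0.82. Of its measured genes 2 of 6 were at least 2-fold higher at 24 h and 1 of 5 lower at 48 h, and the others lay within 2-fold.

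Germ cell-like cells, marked by NANOS3, TFAP2C and KIT, were 7.31 and 4.27 times as frequent with A+B first as with BMP4 first at 24 h and 48 h of A+B. Depth was argued against for the marker combination: at 6000 UMIs per cell the share with SOX17, TFAP2C and NANOS3 still differed 12.0 and 7.61 times. This rested on 10 and 15 cells with BMP4 first. For the class shares themselves depth was not tested, since cells were not clustered again at equal depth. The filter on cells stayed open, because over every barcode the ratios were 6.19 and 2.75, and the lower lay between the bounds of 1.5 and 3 set for the test. An effect of order, or of the last cue, on germ cell-like fate may also stand behind the pattern and stays open, with 1 library per condition.

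Cluster 9, with SOX17 and PRDM1 but little FOXA2, had 87.7% of its cells from sustained A+B. Doublets were argued against, as its cells there had 1.04 times the median UMIs of the library's other cells. With the library clustered alone, 569 and 298 of these cells fell in 2 clusters of 788 and 374 cells. Cluster 9 made up 72.2 and 79.7% of those clusters, and the rest came from other clusters. The endoderm-like share of the library was 49.8% with marker genes allowed and 49.3% with doublets kept, against 26.0% as reported. Whether cluster 9 is a group apart from endoderm-like cells thus stays open. Germ cell genes were present too. TFAP2C was at 78.8 CPM in cluster 9, 287 CPM in germ cell-like and 6.60 CPM in endoderm-like cells over all libraries. NANOS3 was at 15.5, 48.4 and 1.39 CPM, and KIT at 33.4, 37.2 and 39.0 CPM. The germ cell-like share of the library also rose in some alternative clusterings, as given above. Whether the cluster is apart from germ cell-like cells was not tested and stays open. A shift of the whole library was not tested, and whether the cluster may reflect 72 h of A+B as such, or this culture, stays open too.

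In endoderm-like cells after A+B for 24 h then BMP4, MSX1, HAND1, ACTC1 and 7 other genes stood highest over sustained A+B. Free RNA was argued against for the 10 genes as a set, since pluripotent-like cells of the same library held a median of 8.71% of the endoderm-like level; ITGA6 was higher in them (122 against 64.4 CPM), but at 4.11 CPM in lateral or extraembryonic mesoderm-like cells, above which free RNA alike in all cells cannot lie. Nascent or paraxial mesoderm-like cells mixed in were argued against for the set too: the mesoderm markers reached 8.67% of the mesoderm-like level and the 10 genes 416%, a ratio of 0.0208. Lateral or extraembryonic mesoderm-like cells, with 2550 CPM of ACTC1 against 84.8 CPM in endoderm-like cells, were too few there to supply MSX1 (321 and 110 CPM), RGS5 (596 and 166 CPM) or TMEM88 (592 and 79.3 CPM). Such cells stay open for ACTC1 and HAND1, nascent mesoderm-like cells for HAND1 (13.6% of their level, against 12.0% for MESP1) and germ cell-like cells for HPGD (1010 CPM), and an effect of BMP4 after A+B may add to these. Amnion-like cells of that library, with 2064 CPM of ACTC1 and 1118 CPM of HAND1, were not tested and stay open for these genes too.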

How the results depend on the processing

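The tests that left out cells under 0.5% mitochondrial UMIs and named clusters at 2 times were chosen only after the data were seen. No paired analysis was possible because each condition had 1 library. Counting error limited genes with few UMIs, and 92 endoderm-like cells with sustained BMP4 were too few for expression. The order of the endoderm-like share kept its direction in every setting for sustained A+B over sustained BMP4 (8.58 to 17.0 times) and for A+B first over BMP4 first (1.33 to 1.52 times at 24 h, 2.32 to 3.24 at 48 h). Counts of genes at least 2-fold apart between whole libraries stayed within 1.5 times in all 112 alternatives. Of 336 alternative class shares 133 lay outside the interval of the value reported, and of 2120 log2 ratios of named genes 487 moved and 2 reversed, both HPGD. For each value below the cause was not tested.

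With gates of at least 2 UMIs, SOX17 with FOXA2 was found in 0.393, 1.12, 0.487, 2.43, 0.745 and 5.04% of cells, in the library order of the report, and without thinning in 2.59, 8.16, 3.78, 16.8, 5.04 and 30.5%. At resolution 0.3 the endoderm-like share with sustained A+B was 34.2%, and 0 genes were at least 2-fold higher in endoderm-like cells after BMP4 for 24 h. With marker genes allowed the endoderm-like share was 6.21% for A+B 24 h first, 4.58% for BMP4 48 h first, 6.31% for BMP4 24 h first and 49.8% for sustained A+B. In those cells 0 genes were higher and 19 lower after BMP4 for 24 h, 61 were lower after A+B for 48 h, HPGD after A+B for 24 h had a log2 ratio of -0.80, and the endothelial or haemogenic list after A+B for 48 h a median of -0.54. With 4000 variable genes the share with sustained A+B was 36.0%, and 0 and 6 genes were higher after BMP4 for 24 h and 48 h. Over every barcode the shares were 2.16% for sustained BMP4, 4.14% for A+B 24 h first, 3.13% for BMP4 48 h first and 11.1% for A+B 48 h first; 0 genes were higher after BMP4 for 24 h, and 5 higher and 28 lower after BMP4 for 48 h. With doublets kept the shares were 4.52% for BMP4 48 h first, 15.4% for A+B 48 h first, 6.24% for BMP4 24 h first and 49.3% for sustained A+B. In those cells 1 gene was higher and 18 lower after BMP4 for 24 h, 30 were lower after BMP4 for 48 h and 58 after A+B for 48 h, HPGD after A+B for 24 h had a log2 ratio of -0.76, and the endothelial or haemogenic list a median of -0.22.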

Other observations

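The tests of lists within classes other than endoderm-like were chosen only after the result was seen. NODAL and its targets were lower with A+B first, and so with BMP4 alone at the end, in other classes too. In pluripotent-like cells 4 of 6 measured Nodal-Activin response genes were at least 2-fold lower at 24 h of A+B and 5 of 6 at 48 h (median log2 ratios -1.81 and -2.46). Some of these were low there: CER1 was at 1.02 against 10.9 CPM at 24 h, and MIXL1 at 1.03 against 10.1 CPM at 48 h. In mesoderm-like cells they were at 488 against 2226 CPM and 313 against 1047 CPM. Free RNA as a source of such low levels was not tested. In nascent or paraxial mesoderm-like cells 7 of 9 and 8 of 9 were lower (-1.73 and -1.74), and in germ cell-like cells 4 of 8 and 6 of 8 (-1.33 and -2.55). NODAL itself was at 9.87 against 29.5 CPM and 8.63 against 30.2 CPM in pluripotent-like cells, and at 26.6 against 93.5 CPM and 8.96 against 96.0 CPM in germ cell-like cells. In amnion-like cells at 24 h of A+B NODAL was lower with A+B first as well (0.819 against 3.44 CPM, under the minimum for a measured gene), but of 6 measured genes 3 were higher and 1, CER1, lower (median 0.71).

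Cluster 11 carried the forebrain and neural genes SIX3 (107 CPM) and HESX1 (219 CPM) with SOX2 at 546 CPM. Of the neural list besides SIX3, PAX6 was at 8.81 CPM and the other members at 2.05 CPM or less. The pluripotency genes POU5F1 (697 CPM) and DNMT3B (422 CPM) were also present, and the cluster stayed unnamed. Cluster 11 held 3.81, 5.34, 3.90, 1.06, 0.295 and 0.211% of cells in the library order of the report.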
